A study of Mus musculus with 8 samples.

How the data were processed

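Total RNA was taken from flank skin of 8 mice, 4 immune and 4 naive, labelled with biotin after amplification and hybridised to Illumina bead arrays, per the labels' protocols. The series' design text counts 4 mice per condition, so each array is a separate animal. The replicate numbers come from the sample titles. The table of the scanner's output as deposited holds a mean bead intensity for each of 25697 probes on each array, on a linear scale, with no subtraction of background and no normalization between arrays. Beside each intensity the deposited table gives a detection p-value, per the file headers, which sets the probe against the array's negative controls. GenomeStudio 1.8 is named in the submitters' processing notes, and further steps are not given in the sources used here. A second table holds the authors' processed intensity values of the same arrays. Set against the scanner values, each of its 8 columns ranked most like its own array. Its sorted columns lay within 2.79% of the mean of the sorted scanner columns, and its column medians lay between 210.9 and 211.3. This is close to what quantile normalization on a linear scale without background subtraction would give. The method is inferred, as the sources used here do not state it. The direction of the values follows from this match, and centring does not apply to linear values. Median scanner intensities lay between 203.6 and 218.3 per array.

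Intensities were corrected for background and normalized with neqc in limma 3.58.1 under R 4.3.3. This fits a normal and exponential convolution with background parameters inferred from the detection p-values, adds an offset of 16, applies quantile normalization and takes log2. A probe entered if its detection p was under 0.05 on at least 4 arrays, which 12164 probes met. Probe to gene pairs came from GEO's platform annotation, and symbols were updated by gene number through RefSeq genes of assembly GRCm38.p6, used for names only. Exactly 1 symbol was given for 23978 probes, several for 0, and 1719 probes are unnamed here. Of the named probes 23962 matched by gene number. Of the entering probes 11469 had a name, and each of 8889 genes was represented by its entering probe with the highest mean level. Of 1988 genes with several entering probes, none had probes that passed in opposite directions. Of 231 such genes that passed, 155 had another probe that did not pass. No genome build is given in the sources used here, so no positions are printed.

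The comparison was immune minus naive with limma's lmFit and eBayes with a trend, two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The fit had no covariate. Errors of log2 fold changes are the fit's moderated standard errors, and levels are given as mean and SD over 4 arrays. Where a probe was detected on no array of a group, its fold is given as at least N-fold. This sets the detected group's mean against the other group's mean of, per array, the higher of the probe's own value and the lowest log2 value among detected probes. Other folds of genes near background depend on the background correction. The highest log2 value was 16.1 on every array.

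Gene lists were fixed before the data were examined, as were the tests, the rule for named genes and all but 2 of the other settings listed below. There were 38 lists without shared members, and the 35 with at least 3 tested genes were tested with camera at a preset correlation of 0.01, again with an estimated correlation and on ranks, and with fry. Per-array list means, each gene centred on its 8-array mean, were compared by a two-sided exact permutation test over 70 arrangements of the arrays. Named genes are the 12 largest increases and the 12 largest falls among genes that passed and whose groups did not overlap, 12 genes fixed beforehand, and up to 4 members with the smallest p of each list. That number was set at 2 for lists that did not pass camera, after the data were seen. Genes named outside this rule were chosen after their values were seen. They are Wars and Cxcl14, the genes not tested that were detected in a single group, those past the threshold in every fit without 1 array, and those named only in the closing part.

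The alternatives changed background correction, offset, normalization, source of the values, probe filter, probe choice, variance model, array weights, the list test and the threshold, added the replicate number as a block or the per-array mean of the muscle or hair list as a covariate, and left out each array in turn. An alternative with slides as a block was planned and not run, as the tables used here name no slides. Leaving out the 3 arrays with the highest hair list means (the 3 hair arrays below), and fitting both covariates together, were added after the data were seen. The fit was tested on simulated data drawn from the means and residual SDs of the 8889 genes with 200 genes changed. It recovered 65.0% of genes changed 2-fold and 86.0% of those changed 4-fold, with 6.21% of calls false, and called 0 lists when none was shifted. These simulated genes vary independently, unlike those on the arrays.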

Results

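Leishmania major is a protozoan parasite that lives inside macrophages, and the study's title concerns CD4 T cells that stay in the skin and protect against a new infection with it. Transcript levels were measured in flank skin of female C57BL/6 mice on Illumina bead arrays, on which each probe reports the brightness of a transcript's labelled copies. The series compares 4 immune mice with 4 naive mice of matched age, 1 array per mouse. The immune mice had received 2000000 parasites in an ear about 14 weeks before they were challenged with the parasite in the flank. About 50 mg of skin was taken at the challenge site 12 hours later. The protocol in the labels says that naive mice were challenged too, while the naive samples' own tissue label mentions no challenge. The comparison therefore asks how skin of previously infected mice differs from skin of naive mice 12 hours after parasites entered it, as far as the protocol is read that way.

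Between 44.8% and 49.2% of the 25697 probes were detected on each array, and 8889 genes were tested. The number of arrays limits the precision. The first principal component held 46.5% of the variance and placed the immune arrays between 6.35 and 54.1 and the naive arrays between -39.2 and -15.7. Rank correlations of the scanner intensities of all 25697 probes, detected or not, ran from 0.918 to 0.931 among immune arrays. They ran from 0.932 to 0.941 among naive arrays and from 0.909 to 0.934 between groups.

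Among genes that passed the test and whose groups did not overlap, Cxcl9 and Cxcl10, chemokines induced by interferon-gamma that draw activated T cells, rose the most. Cxcl9 had a log2 level of 13.19 ± 1.84 in immune skin and 6.09 ± 0.46 in naive skin (SD, n = 4 each), a log2 fold change of 7.10 ± 0.76 (SE; limma, adjusted p = 0.00485). Cxcl10 rose by 5.58 ± 0.45 (SE; adjusted p = 0.00244), from 6.00 ± 0.66 to 11.58 ± 0.86 (SD, n = 4). Naive levels of both lay near background, with Cxcl9 detected on 2 and Cxcl10 on 1 of the 4 naive arrays. Ptx3, a soluble pattern recognition protein, rose 28.6-fold, the interferon-inducible GTPases Igtp and Gbp2 17.1-fold and 16.7-fold, and Saa3, an acute phase protein, 15.4-fold. Cd274, which encodes the inhibitory ligand PD-L1, rose 11.9-fold, and the transcription factor gene Batf2 10.3-fold. The 12 largest increases among genes whose immune arrays all lay above the naive arrays also held Calhm6, AA467197, the monocyte chemokine gene Ccl12 and Upp1, a uridine phosphorylase, with log2 fold changes of 3.92, 3.38, 3.23 and 3.18. All 4 immune arrays lay above all 4 naive arrays for each of these 12 genes. Ptx3, Calhm6 and Batf2 were each detected on 2 of the 4 naive arrays and AA467197 on 3, so their folds also depend on the background correction.

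**Figure D1:**
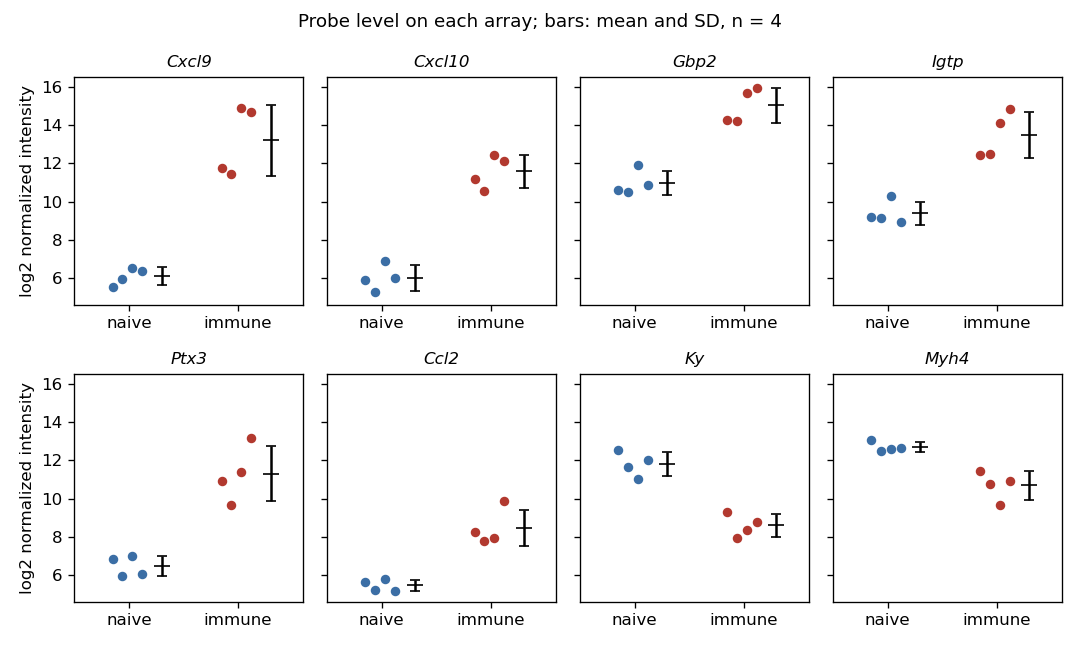
Log2 normalized intensity of 8 named genes on each array (points; red for the 4 immune, blue for the 4 naive mice), with the group mean and SD beside the points. Cxcl9, Cxcl10, Gbp2, Igtp, Ptx3 and Ccl2 lay higher on all 4 immune arrays than on any naive array, and Ky and Myh4 lay lower on all 4.

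Of the 17 tested genes of the interferon-gamma response list, 16 rose and none fell, by log2 fold changes from 1.08 to 7.10, and all 17 rose when adjusted over the list alone. Wars, at 0.81 ± 0.26 (SE; adjusted p = 0.0768), was the member that missed the threshold over all genes, named after its value was seen. The list included the GTPase Gbp7, at 2.75 ± 0.30 (SE). The list mean was 2.92 higher in immune skin on the log2 scale (two-sided exact permutation p = 0.0286, n = 4 against 4, the smallest p this design can give; 0.1 after adjustment over 35 lists). With the mean of the skeletal muscle list per array as a covariate it was 1.82, and no gene passed. Arrays of immune mice 1 and 2 had list means of 0.72 and 0.59 around the 8-array mean, immune mice 3 and 4 had 1.97 and 2.55, and the naive arrays lay between -1.76 and -1.01.

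Genes of MHC class I antigen processing, which load peptides for display to CD8 T cells, rose in 11 of 15 cases (12 when adjusted over the list alone). The peptide transporter gene Tap1 rose by 1.77 ± 0.28, the immunoproteasome subunit Psmb8 by 1.47 ± 0.25, H2-T23 by 1.15 ± 0.19 and Psme1 by 0.91 ± 0.15 (log2, SE). Of the 18 antiviral genes of the type I interferon response, 7 rose (11 adjusted over the list alone), among them Isg15 by 2.55 ± 0.54, Ifit2 by 2.34 ± 0.51 and Ifit3 by 2.11 ± 0.41. Oas3 was not detected on any naive array and was at least 1.39-fold higher in immune skin (adjusted p = 0.0195). No member of either list fell. None of the 9 tested genes of MHC class II antigen presentation passed the test (limma; 0 at an unadjusted p under 0.05), with Cd74 at 1.03 ± 0.49 and H2-Aa at -0.62 ± 0.29.

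Chemokines that draw monocytes and lymphocytes rose in 5 of 16 cases (5 adjusted over the list alone). Ccl12 rose by 3.23 ± 0.44, Ccl7 by 2.53 ± 0.53, Ccl19, a ligand of the receptor CCR7, by 2.30 ± 0.25 and Cxcl14, named after its value was seen to complete the count, by 1.14 ± 0.26 (log2, SE). Ccl2, the main monocyte chemoattractant, was detected on all 4 immune arrays and on no naive array, and was at least 5.48-fold higher in immune skin (adjusted p = 0.0105). Ccl5 was 1.82 ± 0.75 higher without passing the test (adjusted p = 0.141). Among the 4 tested genes listed as neutrophil chemokines and growth factors Cxcl1 rose by 2.56 ± 0.60 (1 adjusted over the list alone). Pf4, which is in this list although it encodes a platelet chemokine, stood at -0.81 ± 0.49. Of the endothelial activation genes, those of the adhesion molecules ICAM1 and VCAM1 (Icam1 and Vcam1) rose by 2.38 ± 0.33 and 1.82 ± 0.45, 2 of 5 tested members (2 adjusted over the list alone), whereas Ackr1 and Selp, at 0.40 ± 0.24 and 0.30 ± 0.23, did not pass.

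Markers of myeloid cells went both ways. Of 15 neutrophil markers 3 rose (4 adjusted over the list alone), the formyl peptide receptor gene Fpr2 by 2.67 ± 0.43 and the lectin receptor gene Clec4d by 2.02 ± 0.56 (log2, SE). The third, Clec4e, was not detected on naive arrays and was at least 1.99-fold higher in immune skin. S100a8, at 1.73 ± 0.56, missed the threshold (adjusted p = 0.0768). Of 16 monocyte and macrophage markers the Fc receptor genes Fcgr4 and Fcgr1 and the monocyte gene Plac8 rose by 2.24 ± 0.43, 1.63 ± 0.42 and 1.68 ± 0.40, and Cd163, a scavenger receptor of resident macrophages, fell by 1.92 on the log2 scale (SE 0.52; 3 higher and 1 lower adjusted over the list alone). The immune mice parted in the mean of this list, at 1.04 and 0.60 on arrays 1 and 2 and -0.28 and -0.63 on arrays 3 and 4. Naive arrays lay between -0.64 and 0.38. Of 13 inflammatory cytokines and early mediators 3 rose (6 higher and 1 lower adjusted over the list alone), Bcl3 by 1.52 ± 0.34, Il15 by 1.07 ± 0.21 and Nfkbia by 0.78 ± 0.17, with Osm at 1.72 ± 0.53 (adjusted p = 0.0649). Of 11 microbicidal effector genes 1 rose, the hexokinase gene Hk3 by 2.19 ± 0.22 (2 adjusted over the list alone), while Lcn2, Cyba and Gch1 stood at 1.75 ± 0.53, 0.76 ± 0.30 and 0.60 ± 0.23. Of 7 dendritic and Langerhans cell markers Cd40 rose by 1.77 ± 0.38 (1 adjusted over the list alone) and Siglech stood at -1.07 ± 0.39.

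Only 9 of 24 listed T cell markers were tested, as the others had no named probe past the detection filter. None of the 9 passed the test (limma; 0 adjusted over the list alone; 0 higher and 2 lower at an unadjusted p under 0.05), and the list mean was -0.27. Cd3e stood at -0.67 ± 0.26 (SE; adjusted p = 0.121) and Trat1 at -0.94 ± 0.36. Cd4 was detected on 0 of the 8 arrays and was not tested. Cd6 and Cd28 of the same list and Cd8b1 of the cytotoxic list, named after their values were seen, were detected on 2 immune arrays and 0 naive arrays by 1 probe each, out of 4, 3 and 2 probes, and on no array by their other probes, and were not tested either. Of the 2 probes for Ifng, 1 was detected on immune arrays 3 and 4, at log2 levels of 8.55 and 7.89, and on no other array. The Tnf probe was detected on the same 2 arrays, at 7.21 and 8.10. Nos2, the inducible nitric oxide synthase, was detected on 1 immune array and Il4 on 2 naive arrays, so that neither was tested. Il10 differed by 0.30 ± 0.43 (adjusted p = 0.678). Its levels lay near background, with detection on 3 immune and 2 naive arrays, so a difference could be missed. Among 20 genes listed for cytotoxic lymphocytes 6 were tested and none passed (0 at an unadjusted p under 0.05), with a mean of -0.02 and a median of 0.17 (Klrd1 -0.72 ± 0.35, Nkg7 0.34 ± 0.20). Only 4 of 11 listed tissue residency genes were tested and none passed (2 adjusted over the list alone), with the early activation marker Cd69 at 2.25 ± 0.64 (adjusted p = 0.052) and Litaf at 0.47 ± 0.15. None of 3 lymphocyte recirculation genes (Satb1 -0.55 ± 0.23, Il7r 0.30 ± 0.28) and none of 8 genes of the interleukin 17 axis (Rora -0.76 ± 0.27, Il17rb -0.44 ± 0.21) passed, with 1 lower at an unadjusted p under 0.05 in each. Il17rb lay near background, between 5.67 and 6.78 over all arrays. Of 10 regulatory T cell and inhibitory genes 2 rose (2 higher and 1 lower adjusted over the list alone), the receptor genes Il10ra by 1.29 ± 0.32 and Tnfrsf18 by 0.94 ± 0.21, both of which other leukocytes express too, while Ikzf2 stood at -1.22 ± 0.41. On immune arrays 2, 3 and 4 Ikzf2 lay between 5.29 and 5.37, under the lowest level of detected probes. Of 11 genes of T helper 2 cells and alternative activation, the eosinophil chemokine gene Ccl11 rose by 1.26 ± 0.31 and Arg1 stood at -0.55 ± 0.17 (adjusted p = 0.0619); 2 were higher and 2 lower adjusted over the list alone.

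Some genes of muscle, fat, vessels and nerve were lower in immune skin. Camera called the skeletal muscle, adipocyte, endothelial and Schwann cell lists lower with a preset correlation and none of them with an estimated correlation (adjusted p = 0.480 for skeletal muscle and 0.423 for each of the others). Ky, a gene of muscle maintenance, fell the most, by 3.20 on the log2 scale (SE 0.36; limma, adjusted p = 0.00485), from 11.79 ± 0.62 to 8.59 ± 0.59 (SD, n = 4 each). The 12 largest falls among genes without overlap of the groups ran from this value to -1.97 and included Myh4, the heavy chain of fast muscle fibres, at -2.00 ± 0.33, Lmod1 of smooth muscle at -2.43 ± 0.38, Stac3, which couples excitation to contraction, at -2.19 ± 0.41, and Prkaa2, a catalytic subunit of AMP-activated kinase, at -2.23 ± 0.35. The others were Pon1, Abca9, Ddit4l, Cyp2e1, Fam180a, Pamr1 and Tmem25, which were 5.86-fold, 5.78-fold, 5.75-fold, 4.51-fold, 4.27-fold, 3.98-fold and 3.91-fold lower. Abca9 was detected on 2 of the 4 immune arrays and Pon1 and Pamr1 on 3, so their folds also depend on the background correction. Of 20 skeletal muscle genes 7 fell (9 adjusted over the list alone) and none rose, among them Actn3 by 1.04, Ttn by 1.01 and Mybpc2 by 0.87 on the log2 scale, and the list mean was -0.60. Of 12 adipocyte genes 4 fell (8 adjusted over the list alone), namely Gpd1 by 1.10, Plin4 by 0.85, Lpl by 0.75 and Pnpla2 by 0.47, with a list mean of -0.67. Of 13 endothelial cell markers 3 fell (5 adjusted over the list alone), Emcn by 1.28, Esam by 0.86 and Egfl7 by 0.61, with a list mean of -0.48 and Flt1 at -0.75 ± 0.26 (SE). Of 5 Schwann cell and nerve genes Ncmap fell by 1.01 (2 adjusted over the list alone), the list mean was -0.69, and Drp2, Mbp and Pmp22 stood at -0.99 ± 0.28, -0.72 ± 0.32 and -0.54 ± 0.25. Of 8 smooth muscle and pericyte genes Lmod1 and Des fell (3 adjusted over the list alone), Des by 0.67, with a list mean of -0.53. Of 16 fibroblast and matrix genes Col1a2 fell by 0.72 (2 adjusted over the list alone), Dpt stood at -1.09 ± 0.31 (adjusted p = 0.0505), and the list mean was -0.23. Of 8 mast cell, basophil and eosinophil markers the mast cell protease gene Cpa3 fell by 1.12 (1 adjusted over the list alone) and Fcer1a stood at 0.58 ± 0.29. Fcer1a lay near background, between 5.21 and 6.51 over all arrays.

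**Figure D2:**
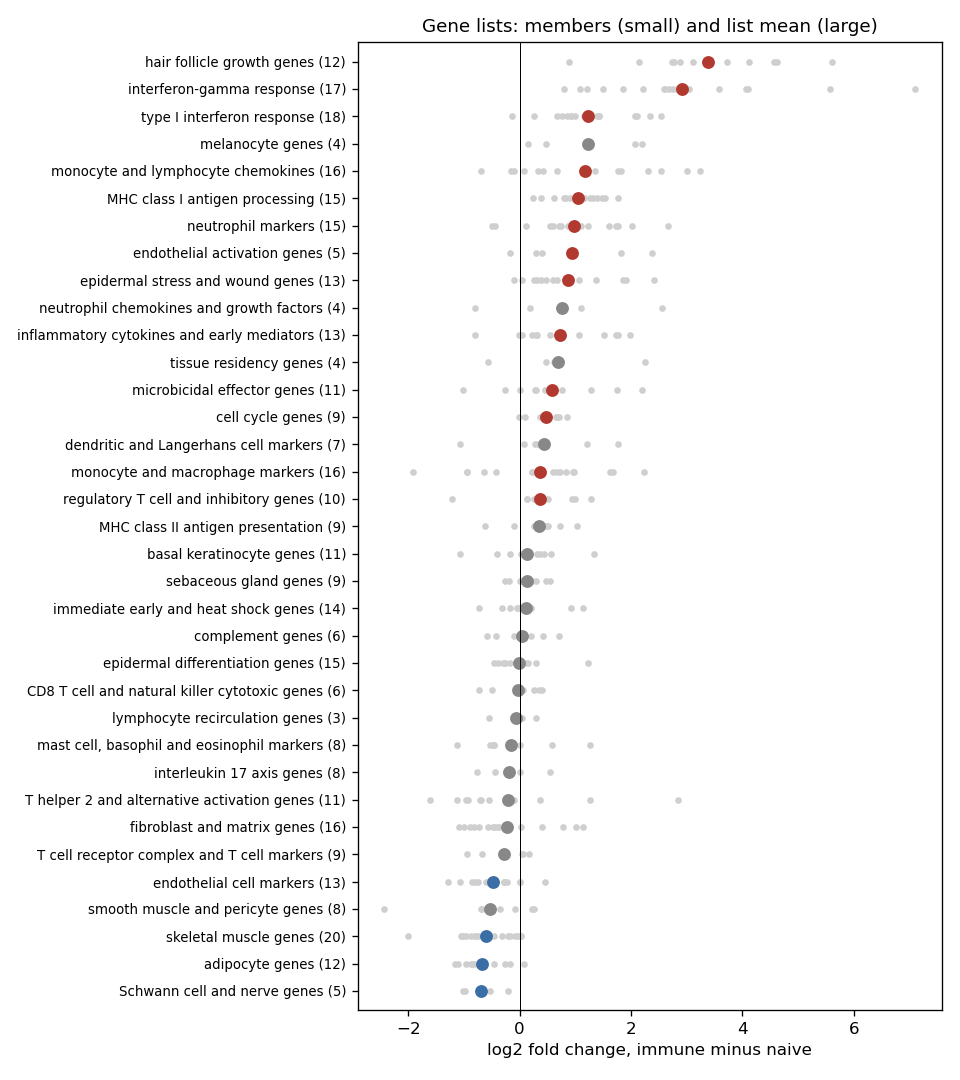
Log2 fold changes, immune minus naive, of the members of each gene list (small points) and the list mean (large points; red or blue where camera's adjusted p with the preset correlation was under 0.05, grey otherwise), with the number of tested members in brackets. The interferon-gamma response list has a mean of 2.92 with every tested member above 0, and the hair follicle growth list a mean of 3.38 with no member past the gene-level test.

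Hair follicle growth genes differed widely between single mice. The list mean was 3.38 higher in immune skin on the log2 scale, yet 0 of its 12 tested genes passed the test (limma; 0 adjusted over the list alone; 4 higher at an unadjusted p under 0.05). The hair keratin genes Krt71, Krt34, Krt27 and Krt73 stood at 5.61 ± 1.95, 4.62 ± 2.02, 4.57 ± 1.66 and 4.11 ± 1.63 (SE; adjusted p from 0.0917 to 0.159). Immune mice 2 and 3 had list means of 3.01 and 5.86 around the 8-array mean, naive mouse 2 had 0.77, immune mouse 1 had -0.21 and immune mouse 4 had -1.91, and the other naive mice lay between -2.57 and -2.42. In immune mouse 3 the mean of 4 melanocyte genes was 4.03 and that of 9 cell cycle genes 1.20. None of these melanocyte genes (Dct 2.20 ± 1.33, Pmel 2.08 ± 1.34; 0 at an unadjusted p under 0.05) and none of these cell cycle genes (Rrm2 0.70 ± 0.22, Mcm5 0.85 ± 0.28, Tyms 0.68 ± 0.25, Mcm2 0.37 ± 0.20; 3 higher at an unadjusted p under 0.05) passed.

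Few epidermal genes passed the test. None of 15 epidermal differentiation genes passed (0 at an unadjusted p under 0.05; Lce1c -0.38 ± 0.17, Lce1b -0.26 ± 0.13) and their mean was -0.002. Of 11 genes listed as basal keratinocyte genes Sfn rose by 1.34 ± 0.37 (adjusted p = 0.0499, and 0 adjusted over the list alone) and Trp63 stood at 0.36 ± 0.12. Sfn is not confined to the basal layer, so its rise does not mark basal cells. None of 13 epidermal stress and wound genes passed (4 higher at an unadjusted p under 0.05), with Krt6b, Stfa1, Il24 and Krt16 at 2.41 ± 0.81, 1.91 ± 0.83, 1.85 ± 0.65 and 1.38 ± 0.59. None of 9 sebaceous gland genes (Krt79 0.48 ± 0.22, Elovl4 0.30 ± 0.15; 0 at an unadjusted p under 0.05) and none of 6 complement genes (C4b -0.43 ± 0.18, Cd55 -0.59 ± 0.29; 1 lower at an unadjusted p under 0.05) passed. Of 14 immediate early and heat shock genes Junb rose by 1.14 ± 0.28 and Zfp36, which destabilises cytokine transcripts, by 0.92 ± 0.13 (2 higher and 1 lower adjusted over the list alone).

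Set against all other genes by limma's camera test with a preset correlation, 13 lists stood higher and 4 lower in immune skin (adjusted p under 0.05). With an estimated correlation no list passed (smallest adjusted p = 0.291; 4 lists at an unadjusted p under 0.05). With the preset correlation the lowest adjusted p was 2.75e-17 for the interferon-gamma response, then 2.61e-10 for MHC class I antigen processing, 3.21e-08 for the type I interferon response and 4.03e-05 for monocyte and lymphocyte chemokines. Hair follicle growth genes (0.000311), neutrophil markers (0.000720), inflammatory mediators (0.00259), epidermal stress genes (0.00443), microbicidal genes (0.0144), cell cycle genes (0.0167), endothelial activation (0.0243), regulatory T cell and inhibitory genes (0.0291) and monocyte and macrophage markers (0.0426) followed. Lower were skeletal muscle genes (0.000206), adipocyte genes (0.00120), endothelial cell markers (0.0251) and Schwann cell and nerve genes (0.0365). The adjusted p with an estimated correlation was 0.361 for the interferon-gamma response and 0.590 for monocyte and macrophage markers. fry's directional test, which asks whether a list's genes move on balance in a single direction without reference to other genes, passed 5 lists higher and 4 lower. These were the interferon-gamma, MHC class I, chemokine, microbicidal and endothelial activation lists and the adipocyte, endothelial, Schwann cell and smooth muscle lists. In 10 lists, among them the first 2 of these, the array means of the groups did not overlap (exact permutation p = 0.0286 each, 0.1 adjusted). Camera's call was lost for monocyte and macrophage markers without immune array 1 (adjusted p = 0.383), immune array 2 (0.129), naive array 1 (0.125) or naive array 2 (0.0533). It was lost for endothelial cell markers without immune array 3 (0.0540), immune array 4 (0.0530) or naive array 2 (0.0836) and for Schwann cell genes without immune array 3 (0.0575) or naive array 2 (0.0533). The same holds for cell cycle genes without immune array 3 (0.144) and for regulatory T cell genes without immune array 4 (0.0699) or naive array 1 (0.0524). It was also lost with detection p under 0.01 on all 8 arrays for neutrophil markers (0.0816), monocyte and macrophage markers (0.0881) and Schwann cell genes (0.280). No detection filter ended it for regulatory T cell genes (0.111) and cell cycle genes (0.0592). With the mean of a gene's probes it was lost for monocyte and macrophage markers (0.0796) and Schwann cell genes (0.0881). With all probes tested singly it was lost for monocyte and macrophage markers (0.0746) and with array weights for endothelial cell markers (0.0946). On ranks it was lost for monocyte and macrophage markers (0.0670) and endothelial activation (0.0593). The hair covariate ended the calls of Schwann cell genes (0.137) and cell cycle genes (0.772). The muscle covariate ended those of the regulatory T cell (0.213), neutrophil (0.221), inflammatory (0.139), microbicidal (0.0626), endothelial activation (0.0674), endothelial (0.747), epidermal stress (0.553), hair follicle (0.0663), adipocyte (0.0814), Schwann cell (0.697) and cell cycle (0.553) lists. In the settings added after the data were seen, leaving out the 3 arrays with the highest hair list means ended the calls of endothelial cell markers (0.0911), Schwann cell genes (0.109) and cell cycle genes (0.229). Both covariates together ended those of the regulatory T cell (0.0995), endothelial (0.659), epidermal stress (0.433), adipocyte (0.125), Schwann cell (0.821) and cell cycle (0.659) lists. Other lists passed only under an alternative. Epidermal differentiation genes, whose sign reversed, passed as higher with the muscle covariate (0.0387) and with both covariates (0.0215), as did MHC class II antigen presentation (0.000295 and 0.000264). With the hair covariate tissue residency (0.0204), basal keratinocyte (0.0280) and immediate early genes (0.0135) passed as higher and smooth muscle genes as lower (0.0114). The last 3 passed with both covariates too (0.0227, 0.0182 and 0.0451). With detection p under 0.01 on all 8 arrays dendritic cell markers (0.0297) and basal keratinocyte genes (0.0483) passed as higher. Without single arrays fibroblast genes passed as lower without immune array 1 (0.0202), basal keratinocyte genes as higher (0.0288) and smooth muscle genes as lower (0.0334) without immune array 3, and MHC class II genes as higher without immune array 4 (0.0464). Without the 3 arrays with the highest hair list means MHC class II and basal keratinocyte genes passed as higher (0.0345 each) and smooth muscle genes as lower (0.0467). Of the 35 splits of the 8 arrays into 4 and 4, 3 gave at least as many lists as the 17 of the real split, whereas 1 gave as many genes, the real split itself. The lists of T helper 1 effector genes, of B cell and plasma cell markers and of erythroid genes had 2 tested members each and were not tested.

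**Figure D3:**
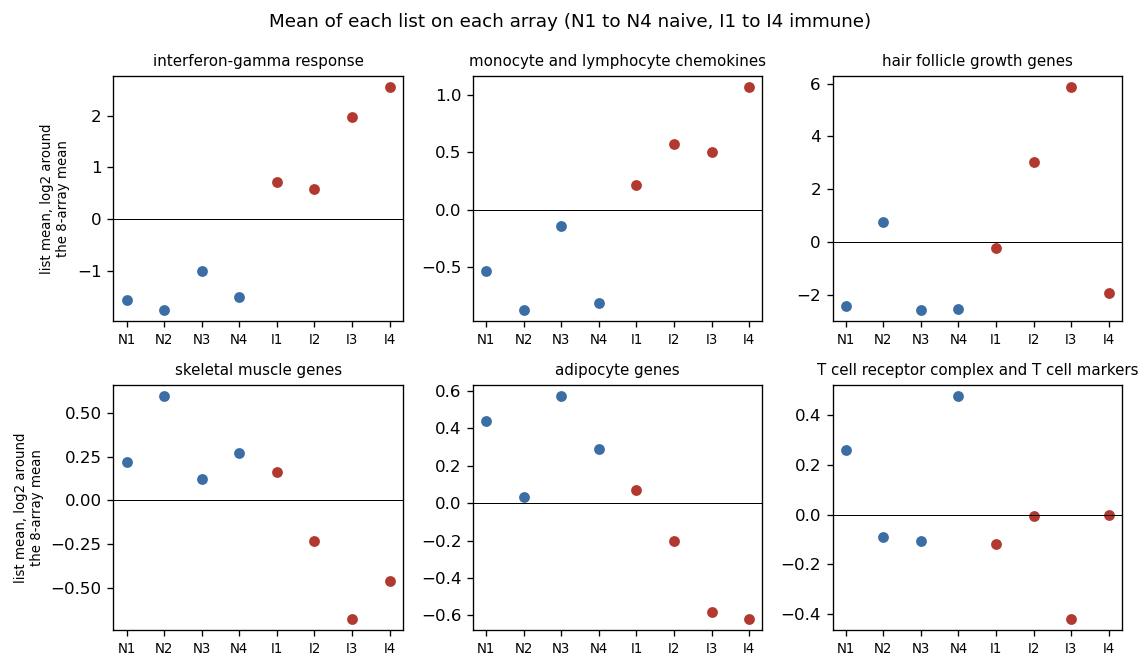
Mean of 6 gene lists on each array, as log2 values around the 8-array mean (blue N1 to N4, naive mice; red I1 to I4, immune mice). The interferon-gamma response list lies between 0.59 and 2.55 on immune arrays and between -1.76 and -1.01 on naive arrays, while the hair follicle growth list ranges from -1.91 to 5.86 among immune mice.

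Over all genes 313 were higher and 614 lower in immune skin at limma's adjusted p under 0.05, out of 8889. Of these, 154 and 264 differed at least 2-fold. Without overlap between the groups were 644 genes higher and 1053 lower, or 19.1% of all genes against 2.86% by chance. In each of the 8 fits without 1 array, 16 genes were higher (Calhm6, Casp1, Casp4, Ccl12, Ccl19, Cxcl10, Cxcl9, Gbp10, Gbp2, Gbp3, Gbp7, Hk3, Icam1, Igtp, Ptx3 and Xdh) and 8 lower (Aifm2, Aldh2, Ddit4l, Fsd2, Igf2, Ky, Mllt11 and Tef). All 313 and 614 genes kept their direction and an unadjusted p under 0.05 in each of these 8 fits. Each fit keeps all but 1 of the arrays that picked these genes, so this looser check adds little. The counts rest on single arrays: they were 84 higher and 123 lower without immune array 2, 120 and 277 without immune array 3, 16 and 8 without naive array 1, and 29 and 22 without naive array 4, and at least 2-fold 66 and 91, 75 and 126, 16 and 7, and 26 and 18, with 441 lower at least 2-fold without immune array 1. With the mean of the skeletal muscle list per array as a covariate no gene passed (limma; 657 higher and 972 lower at an unadjusted p under 0.05), and with the hair follicle list mean 23 were higher and 9 lower.

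**Figure D4:**
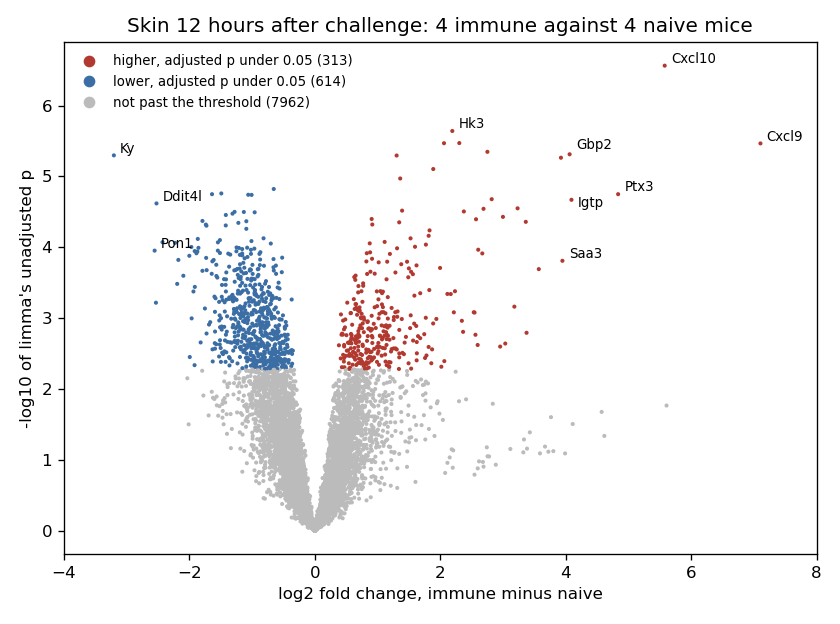
Log2 fold change, immune minus naive (x axis), against -log10 of limma's unadjusted p (y axis) for the 8889 tested genes, each a point (n = 4 mice per group). Red marks the 313 genes higher and blue the 614 genes lower in immune skin at an adjusted p under 0.05, with Cxcl9 at 7.10 and Ky at -3.20.

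Of the 89 genes named in the text that passed the threshold, 24 passed without naive array 1, 29 without naive array 4, 54 without immune array 2, 63 without immune array 3, 72 without naive array 2, 73 without naive array 3, 78 without immune array 4 and 86 without immune array 1. None of them changed direction under an alternative in which it was tested, and 62 of them were tested with detection p under 0.01 on all 8 arrays.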

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

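Of the tests below, those on other splits of the arrays were set before their result was seen, and the use of every test on the 3 weighed patterns (hair follicle genes, genes lower in immune skin, and interferon response genes without T cell markers) was chosen after its values had been seen, although the lists, the muscle covariate, median centring and the fit without background correction had been fixed before the data were examined. The 8 arrays allow 35 splits into 4 and 4. For genes past limma's threshold, 1 of the 35 splits, the real one, reached its 927 genes, and the highest other split gave 204. For genes changed at least 2-fold, 1 split, the real one, reached its 418 genes, and the highest other gave 130. Chance is excluded for both counts only at the smallest share these arrays can give, 1 of 35. The split with 204 and 130 genes set immune 1 to 3 and naive 2 against the rest, which puts the 3 arrays with the highest hair follicle list means on the same side. For gene lists, 3 of the 35 splits reached the 17 of the real split and the highest other gave 19, so chance cannot be excluded for the number of lists.

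A single array far from the other 3 of its group marked 15 of 318 groups of 4 values looked at (35 list means and the named genes, in each group). Chance alone marks about 1 in 20, or 15.9 of them. Naive array 2 stood above the other naive arrays in the hair follicle list mean, at 0.77, and in Krt71, Krt34, Krt73 and Pmel, at log2 levels of 10.82, 11.10, 8.60 and 7.52. Immune array 3 stood above the other immune arrays in the melanocyte list mean, at 4.03, and in Pmel, at 13.32, and below them in Prkaa2, Fam180a and Cd3e, at 6.03, 6.41 and 8.07. Immune array 4 stood above the others in Ccl7, at 12.97, and Gch1, at 12.71. Immune array 1 stood above the others in Ikzf2, at 6.42, and below them in Krt6b, at 12.15. Naive array 3 stood above the others in Vcam1, at 8.52.

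Among list genes that were not tested, 17 were detected on 2 immune arrays and on 0 naive arrays, and 3 on at least 2 naive arrays and on 0 immune arrays, out of 243 probes looked at. Their naive values lie below detection, so only a bound against the lowest level of detected probes can be read beside the difference of the means. The log2 difference and the log2 bound were 2.42 and 1.75 for S100a7a, 1.85 and 0.99 for Slc4a1, 1.33 and 0.85 for Padi3, 1.23 and 0.80 for Ido1, 1.45 and 0.65 for Ifng and 1.31 and 0.52 for Tnf. They were 1.09 and 0.35 for Tgm3, 0.80 and 0.23 for Socs1, 0.88 and 0.20 for Cd6 and 0.97 and 0.14 for Camp. For Ccl17, Mx1, Oas1a, Alas2, Stat4, Cd8b1 and Cd28 the means differed by 0.71, 0.55, 0.46, 0.43, 0.38, 0.32 and 0.12, but the immune mean lay under that level, so no difference is shown. Cd6, Cd28, Stat4, Cd8b1 and Ifng have 4, 3, 3, 2 and 2 probes, of which 1 each was detected and the others on no array. The 3 genes seen the other way, by 1 probe each, were Ccr6, Lipe and Il4, with mean differences of -0.82, -0.59 and -0.49 and log2 bounds of 0.51, 0.15 and 0.04 for the naive mean over that level, and another Ccr6 probe was detected on 2 immune arrays and 1 naive array. These differences were not tested.

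Hair follicle growth genes had a mean 3.38 higher in immune skin with no gene past the test. Whether hair genes rose in every immune mouse cannot be told apart from a difference between single mice: the lowest immune array lay at -2.68 relative to the highest naive array (naive SD 1.64), but this rests on single arrays: it lay 0.51 above without naive array 2, and at -0.99, within that SD, without immune array 4. The genes deviated together within groups, with an estimated correlation of 0.943 against a median of 0.260 over the other lists and 0.792 for the interferon-gamma list. Any shared cause that differs between mice would give this, so it singles out none. The hair cycle stage of single mice is a candidate explanation. List means were highest on immune 2 and 3 and naive 2, but immune 1 had hair keratins too. Krt71, Krt27, Krt73 and Krt34 stood at 10.65, 10.26, 8.29 and 8.85 on immune 1. On naive 2 they stood at 10.82, 10.76, 8.60 and 11.10, and Krt71 lay between 4.89 and 4.96 on the other naive arrays. Infection history as a cause in some of the mice was not tested and stays open. Without immune 2 and 3 and naive 2, in a fit that keeps immune 1, limma passed 1 gene higher (Cxcl10) and 0 lower. At an unadjusted p under 0.05 there were 663 and 1027.

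The 614 genes lower in immune skin had a median log2 fold change of -0.95 (quartiles -1.19 and -0.72). Quantile normalization as the cause is argued against by the 663 genes lower after median centring without it. The adipocyte, endothelial and nerve lists cannot decide on a smaller share of muscle alone. Muscle holds vessels and nerves too and can express genes of the adipocyte list. Together these lists were lower by a difference of -0.61 ± 0.16 (SE). The exact permutation p was 0.0286 (n = 4 against 4), the smallest possible, but camera had already called each of these lists lower. With the muscle covariate, which nearly parts the groups, their means were -0.43, -0.06 and -0.31, so muscle alone is not settled. A smaller share of all deep skin tissue in the immune samples stays open: the muscle, smooth muscle, fat, vessel and nerve list means lay between -0.69 and -0.48. None departed from the other 4 by more than 0.747 standard errors, or by more than 1.11 with the muscle list held to its 12 genes at or under a mean level of 15, whose mean was -0.87. These errors treat the lists as independent although all come from the same arrays, so the check cannot show that the falls were alike. Only 17 of the 614 genes are members of these lists. With the muscle list mean as covariate the median moved from -0.95 to -0.71 and the median standard error from 0.20 to 0.29, and all calls ended, with the change smaller and its error larger; the muscle means nearly part the groups (the lowest naive array lay at -0.0361 relative to the highest immune array), and overlap with the groups was not separated from signal removed or lost degrees of freedom. Infection history, by lowering these transcripts without a change of tissue share, stays open as well and was not tested.

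Interferon-gamma response genes were higher by a mean of 2.92 (1.82 with the muscle covariate, with which no gene passed) while no tested T cell marker passed. Background correction of dim probes is argued against by the mean of 2.22 without it, at which 13 members still passed. The type I interferon list was higher too, by a mean of 1.23. Ifng was not tested, so the rise of the interferon-gamma list does not single out that cytokine. A larger share of T cells in immune skin cannot be told apart from a response of cells already there: the T cell list mean was -0.27 ± 0.17 (SE; at 2 standard errors above this, 1.05-fold), but the tested markers are shared with T cells that normally live in mouse epidermis and could hide a small influx, Cd4 was below detection on all 8 arrays, and 1 of 4 Cd6 probes was detected on 2 immune arrays and 0 naive arrays, the other 3 on no array. Infection history, the difference the design names, stays an open explanation. If the naive mice were not challenged, as their tissue label leaves possible, the challenge itself cannot be told apart from it.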

How the results depend on the processing

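The fits without the 3 hair arrays and with both covariates were added after the data were seen. The 89 named genes past the threshold kept their direction in every alternative in which they were tested (62 of them under the strict filter, detection p under 0.01 on all 8 arrays), and of the lists past camera 1, cell cycle genes, changed sign (-0.0167 with the hair covariate, -0.22 with both covariates). The interferon-gamma list mean ran from 2.55 to 3.21 over the fits without 1 array and was 1.82 with the muscle covariate, with an exact permutation p of 0.0286, the smallest possible, in each setting in which it was computed, except 0.1, the smallest there, without the 3 hair arrays. Probes near background limit the size of folds, as signal left uncorrected holds background in both groups, and covariates and left-out arrays leave fewer degrees of freedom; the causes of other shifts were not tested.

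Leaving out single arrays gave 16 to 390 genes higher and 8 to 798 lower, 16 to 204 and 7 to 441 at least 2-fold, 11 to 13 lists higher and 2 (without naive 2) to 5 lower. The lowest gene counts came without naive 1 and the highest without immune 1. No pairing by number was seen among the mice, which are separate animals: deviations of same-numbered arrays correlated between -0.24 and 0.46, and 1 immune array correlated best with its own number. These few pairs cannot exclude a slide or batch shared by number, as no slides are named. The replicate block gave 235 genes higher and 500 lower, and of the lists ended the call of monocyte and macrophage markers (camera, adjusted p = 0.0552), while dendritic and Langerhans cell markers passed (0.0472).

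Genes higher and lower numbered 199 and 386 with no detection filter, 769 and 1299 with array weights, 23 and 9 with the hair covariate, 0 and 0 with the muscle covariate or both covariates, 14 and 6 at an adjusted p under 0.01, and 1 and 0 without the 3 hair arrays, and 481 probes were higher when tested singly. Limma's unadjusted p under 0.05 held for 657 and 972 genes with the muscle covariate and 718 and 950 with both. At least 2-fold, the counts were 69 and 97 with no background correction and with the authors' processed values, 94 and 174 with detection p under 0.01 on all 8 arrays, 282 and 401 with array weights, 23 and 7 with the hair covariate, 0 and 0 with the muscle covariate or both, 14 and 5 at an adjusted p under 0.01, and 1 and 0 without the 3 hair arrays. Lists higher and lower numbered 7 and 0 with the muscle covariate and 0 and 0 with an estimated correlation, 5 were higher by fry, and 1 was lower with both covariates. With its own mean as a covariate, alone or beside the hair list's, the skeletal muscle list has a mean change of 0 by construction. Its lost call there is therefore not a result. Median centring moved the median of all genes from -0.06 to -0.09.

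Changes of sign otherwise befell only lists and genes that had not passed. CD8 T cell and natural killer cytotoxic genes were at 0.0149 with median centring, 0.0218 with no detection filter, 0.0662 with array weights and -0.11 to 0.0751 without single arrays. Epidermal differentiation genes were at 0.0739 with no filter, 0.10 with weights, 0.36 with the muscle covariate, 0.0883 without the 3 hair arrays, 0.31 with both covariates and -0.0746 to 0.0669 without single arrays. Complement genes were at -0.10 with the strict filter, -0.0677 with weights and -0.0588 to 0.17 without single arrays. Lymphocyte recirculation genes were at 0.13 with the muscle covariate, 0.43 with the hair covariate, 0.30 without the 3 hair arrays, 0.47 with both and -0.27 to 0.14 without single arrays. Fibroblast and matrix genes were at 0.51 with the muscle covariate, 0.30 with both and -0.48 to 0.0731 without single arrays. With the muscle covariate and with both, T helper 2 genes were at 0.19 and 0.23, mast cell markers at 0.17 and 0.25, and melanocyte genes at -0.28 and -1.36, with -0.41 under the hair covariate.

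With the muscle covariate Ccl5, Pf4, Lce1c, Lce1b, Pmel, Mbp, Mcm2, Gsdmd and Nr1d1 were at -0.27, 0.52, 0.0402, 0.0723, -0.13, 0.35, -0.13, -0.27 and 0.28. With the hair covariate Dct, Pmel, Per2, Arntl and Clock were at -0.0788, -0.31, 0.0626, 0.17 and 0.28. With both covariates Ccl5, H2-Aa, Rora, Pf4, Lce1c and Lce1b were at -0.14, 0.24, 0.0417, 0.71, 0.15 and 0.0841, Dct, Pmel, Mbp, Pmp22, Mcm5 and Mcm2 at -1.13, -1.70, 0.36, 0.0732, -0.0721 and -0.18, and Nr1d1, Arntl and Clock at 0.18, 0.33 and 0.27. Per1 was at -0.0431 with array weights and from -0.13 to 0.35 without single arrays. Clock was at 0.0667 without the 3 hair arrays and from -0.34 to 0.0411 without single arrays.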

Other observations

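Of the genes in this paragraph, all were chosen after their values were seen, and no list was tested. The inflammatory caspase genes Casp1 and Casp4 rose by 1.31 ± 0.15 and 1.89 ± 0.22 (log2, SE; adjusted p = 0.00485 and 0.00636), and both were among the genes past limma's threshold in each fit without 1 array. Mlkl, the executor of necroptosis, rose by 2.17 ± 0.42, the death receptor gene Fas by 1.23 ± 0.31 and Casp8 by 0.85 ± 0.20. Gsdmd, which forms the pores of pyroptosis, and Ripk3, the kinase that activates MLKL, did not pass, at 0.38 ± 0.34 and 0.33 ± 0.20. Xdh, which makes uric acid, and Ch25h, which makes an antiviral oxysterol, rose by 1.36 ± 0.17 and 2.36 ± 0.54, and the interferon-inducible GTPases Gbp3 and Gbp10 passed in each fit without 1 array.

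The clock genes Tef, Dbp and Nr1d2 and those set beside them were chosen after their values were seen, and no list was tested. Tef fell by 1.31 on the log2 scale (SE 0.18; adjusted p = 0.0103), Dbp by 1.60 (SE 0.31; adjusted p = 0.0194) and Nr1d2 by 1.67 (SE 0.37; adjusted p = 0.0250), each without overlap between the groups, and Tef passed limma's threshold in each fit without 1 array. Nr1d1 stood at -0.80 ± 0.37, Cry2 at -1.11 ± 0.33, Per2 at -0.32 ± 0.38, Per1 at 0.13 ± 0.29, Arntl at -0.40 ± 0.30 and Clock at -0.17 ± 0.23, and none of these passed (adjusted p from 0.0592 to 0.801). The hour of day at harvest is not given in the sources used here. Among the other genes lower in each fit without 1 array, the growth factor gene Igf2 fell by 1.64, Fsd2 by 1.49, Aifm2 by 1.06, Mllt11 by 1.01 and the aldehyde dehydrogenase gene Aldh2 by 0.65 on the log2 scale.

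The 8 skeletal muscle genes with a mean log2 level above 15 had a mean log2 fold change of -0.21, and the 12 at or under this level a mean of -0.87, where the highest value on every array was 16.1. The level was set after the values were seen. The 2 immune arrays on which Ifng and Tnf were detected, 3 and 4, also had the highest interferon-gamma list means, 1.97 and 2.55, against 0.72 and 0.59 on immune arrays 1 and 2, and the lowest skeletal muscle list means, -0.68 and -0.46 against 0.16 and -0.23. With 4 immune mice no relation between these measures was tested.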
